A study of Bos taurus with 8 samples.

How the data were processed

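Lung RNA from 8 newborn calves was measured on 1-colour Agilent bovine arrays with the dye Cy3. The calves were 4 cloned animals and 4 normal healthy animals, 1 array each, and every sample title gives 4 days, while the series text has the clones dying within that time. Groups and replicate numbers were taken from the sample titles.

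Per the file headers, each deposited scanner file was written by Agilent Feature Extraction, with the background already subtracted from the processed signal. The submitters' processing notes name Agilent Feature Extraction 10.7. The values used were the processed intensity of each spot, in arbitrary linear units that the authors had not normalized between arrays in these files. Flags set by the same program marked spots well above background, saturated spots and outlier spots. The authors' deposited value table held a log2 value per probe. Its columns correlated with the log2 processed signal of the matching array at r of 0.9998 or more. All its columns had the same 75th percentile of 10.54, and their medians were 7.89. These values set the scale as log2, the direction as unchanged and the centring as none, while the step that made the columns alike is not given in the sources used here. The table served only as an alternative. It gave the same counts as quantile normalization, 60 changed probes, 17 genes and 11 lists, so these alternatives are not independent.

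Control spots were left out, as were spots with an outlier flag, between 2 and 21 of 43803 spots per array. No spot was saturated. Log2 processed signal was centred on each array's 75th percentile and averaged over the spots of a probe, which gave 43653 probes. A probe was kept when it was well above background on at least 4 of the 8 arrays, whatever the group, and 35636 were kept. Probe accessions were matched without their versions to a table of bovine RefSeq genes on the assembly ARS-UCD2.0. Of all probes, 23492 obtained 1 gene symbol and 20161 obtained none. Among kept probes, 20741 had a symbol, from 9867 genes, and 14895 had none. The array design names the older build Btau_3.1, so the table gave names only and no coordinates are reported. A gene was represented by its kept probe with the highest mean over all 8 arrays.

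Groups were compared with limma 3.58.1 in R 4.3.3 by lmFit and eBayes with group as the sole term, 2-sided, and p-values were adjusted by the Benjamini-Hochberg method over all kept probes. The threshold was an adjusted p of 0.05. Gene lists with at least 5 measured members were tested on the representative probes by camera with a preset correlation of 0.01. The same lists were tested by camera with the correlation estimated from the residuals and by fry, and members were also counted after adjustment over the list alone. Where the probe of a gene was not well above background on any array of 1 group, a bound is given. The bound set the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the probe's own value and the lowest value of any probe well above background. The bound itself was not tested, and the adjusted p printed with it is that of the fit to the measured values.

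The tests, the 31 gene lists and the rule for named genes were fixed before the data were examined. The rule named the 12 genes with the largest increase and the 12 with the largest decrease among genes past the threshold whose clone and normal values did not overlap, or those that passed where fewer did. Genes named only by a location number, accession or open reading frame were passed over. The rule also named up to 4 measured members of each list with the smallest p, and SFTPA1, SFTPB, SFTPC, SFTPD, ABCA3 and NKX2-1 whatever their p. Only part of the list members it allowed are printed.

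The group comparison and the list tests were run on simulated data with 200 changed probes. These data were built from the means and spreads of 35590 kept probes without missing values. Normalization and filtering were not simulated. With the spread of each group, 12 of 50 probes changed by 1 on the log2 scale were recovered, 29 of 50 changed by 2, 40 of 50 changed by 3 and 45 of 50 changed by 4, and 25 unchanged probes were called among 151 calls. With the pooled spread in both groups, 6 unchanged probes were called among 137 calls. A simulated list of 19 genes shifted by 1 was recovered by camera with either correlation and by fry, and 0 of the other 30 lists were called. The simulated genes varied independently, while the estimated correlation among real cell cycle genes was 0.888. The simulation therefore cannot show how the list tests behave on the real lists.

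Alternatives were quantile normalization, centring on the median of the kept probes, normexp background correction with an offset of 50 before either normalization, no filter and a filter on all 8 arrays, the authors' value table, eBayes with trend and robust settings, array weights, the replicate number as a block, the mean of all probes of a gene, and leaving out each animal in turn. The spot mean was not among the columns used here, so normexp was run on the median signal and median background. Array weights with 1 weight per group, the exact permutation of list scores and the comparison of each clone alone with the normal animals were added after the data were seen. Counts from the last are not given, since a lone clone would have to vary like the normal animals, and the clones varied more. Each slide and each scan run held 4 arrays of 1 group, so slide, scan and group cannot be told apart.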

Results

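Gene expression in lung was compared between 4 cloned calves lost to respiratory failure in their first 4 days and 4 healthy calves described as age-matched, to ask which genes, among them those of surfactant homeostasis, differed between them. Surfactant is the film of lipid and protein that keeps the alveoli open. Between 78.8% and 80.6% of spots were well above background on the clone arrays and between 80.4% and 83.5% on the normal arrays. The log2 75th percentile of the processed signal was 10.49, 10.36, 10.10 and 10.16 in clones 1 to 4 and 10.89, 10.59, 10.85 and 10.85 in normal animals 1 to 4. The age of each clone at death is not given in the sources used here. Relative to the 75th percentile the 10 spike-in controls were all higher on the clone arrays, by a median of 0.67 on the log2 scale. No alternative was centred on the spike-ins. All differences below are therefore relative to the lung probes of the same array, and a change in the level of all of them is not measured. The clones lay on 1 slide and the normal animals on another. Transcripts of the Y-linked genes DDX3Y and USP9Y were well above background in clones 2, 3 and 4, and in neither clone 1 nor any of the 4 normal animals. Of the other Y-linked genes measured, ZFY was well above background in all 8 animals (log2 difference 0.0909) and EIF1AY in 0 of 8. ZFY lay between -2.45 and -1.70 in animals with and without DDX3Y and USP9Y signal, so its probe does not separate them.

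In the lungs of the clones 4 named genes rose and 12 of those named by the rule fell. The increases were in TMEM130, CBLN2, HMGB3 and NLGN2. CBLN2, a secreted organiser of synapses, and TMEM130, a membrane protein, were well above background in all 4 clones and in 0 of 4 normal animals. CBLN2 was at least 15.7-fold higher in clones (adjusted p = 0.0118) and TMEM130 at least 13.7-fold higher (adjusted p = 0.00558). Each adjusted p is that of the fit to the measured values and does not test the bound. The chromatin protein HMGB3 rose from -4.61 ± 0.29 in normal animals to -2.42 ± 0.48 in clones (log2, mean ± SD, n = 4 each), a log2 change of 2.19 (SE 0.27, adjusted p = 0.0238). Both of its probes were called. NLGN2, a neuroligin of inhibitory synapses, rose by 1.54 (SE 0.19, adjusted p = 0.0208), a 2.90-fold increase that 1 of its 2 probes showed at the threshold.

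The largest decrease was that of CYM, which encodes chymosin, the milk-clotting protease of the calf stomach. CYM measured 3.00 ± 0.98 in normal animals and -3.97 ± 1.65 in clones (log2, mean ± SD, n = 4 each), a 125-fold difference (log2 change -6.97, 95% interval -8.82 to -5.11, adjusted p = 0.0180). Its 3 probes had log2 changes of -6.97, -7.44 and -6.75, and the adjusted p of the second was 0.0592. The third was well above background in only 1 of 4 clones, so the size of its change is limited by background. ITIH2, a heavy chain of the inter-alpha-trypsin inhibitors, fell by 3.25 (SE 0.34, adjusted p = 0.0121) and APOC2, the apolipoprotein that activates lipoprotein lipase, fell by 1.68 (SE 0.21, adjusted p = 0.0239). The ITIH2 probe was well above background in 3 of 4 clones and its other called probe in 0, so the size of its decrease is limited by background. ACSM1, an acyl-CoA synthetase for medium-chain fatty acids, fell by 2.69 (SE 0.28, adjusted p = 0.0130) with all 3 of its probes called. PDCL2 fell by 1.82 and ABI3, an adaptor of the actin-regulating WAVE complex, by 1.63 (adjusted p = 0.0172 and 0.0258). The PDCL2 probe was well above background in 3 of 4 clones.

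The remaining 6 named decreases were in genes whose probes were not well above background in any clone, so they are given as bounds. The adjusted p beside a bound is from the fit to the measured values, with the clones at background, and does not test a change of the bound's size. The noradrenaline transporter SLC6A2 was at least 2.95-fold lower in clones (adjusted p = 0.000667) and the photoreceptor nuclear receptor NR2E3 at least 2.85-fold lower (adjusted p = 0.0184). DIO3, the deiodinase that inactivates thyroid hormone, was at least 2.18-fold lower (adjusted p = 0.00477), and the bile acid receptor NR1H4 at least 3.62-fold lower on its brightest probe (adjusted p = 0.0152). The kinase STK32A and the NADPH oxidase NOX5 were at least 1.47-fold and 1.67-fold lower (adjusted p = 0.00437 and 0.0249). Of the 46 probes that fell, 22 were of this kind, as were 5 of the 17 that rose, seen from the normal animals.

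**Figure D1:**
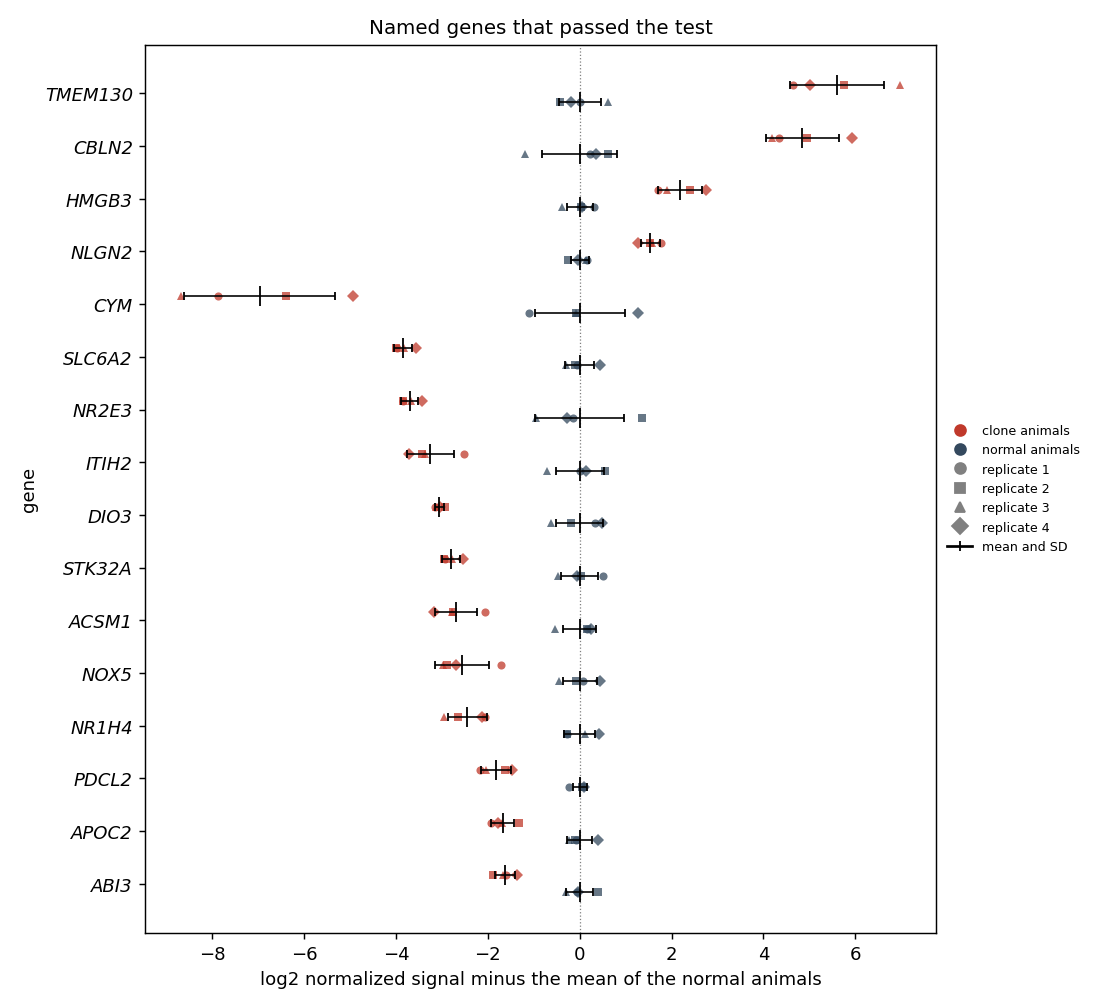
Log2 normalized signal of each named gene that passed the test, as the difference from the mean of the normal animals, for 4 clones (red) and 4 normal animals (dark blue); marker shapes give the replicate and black bars the mean and SD. In each of these genes the 4 clones lie on 1 side of the 4 normal animals, and the clone values of SLC6A2, NR2E3, DIO3, STK32A, NOX5 and NR1H4 and the normal values of TMEM130 and CBLN2 were not well above background.

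Over all genes, 18 of 9867 passed, 4 higher and 14 lower in clones. Of 35636 probes, 63 changed, 17 higher and 46 lower, and all 63 changed at least 2-fold (limma, adjusted p under 0.05). A gene symbol was lacking for 33 of them. Across the alternatives SLC6A2 and TMEM130 passed in 17 of 19, STK32A and DIO3 in 15 of 19, CBLN2 in 14 of 19, CYM and ACSM1 in 14 of 20, ITIH2 in 13 of 19, NR1H4, NR2E3 and PDCL2 in 11 of 19, NLGN2 and APOC2 in 11 of 20, HMGB3 and ABI3 in 10 of 20 and NOX5 in 7 of 19. Genes with a total of 19 were removed by the filter on all 8 arrays, being at background on some arrays, so that setting is not counted for them. Their shares are therefore not comparable with those out of 20. CYM was not called without any 1 of the normal animals, and NOX5 neither with quantile normalization nor in the authors' table. An unadjusted p under 0.05 was reached by 4692 probes, and clone and normal values did not overlap in 3603 probes, or 10.1%. Chance gives 2.86% where both groups vary alike. The clones varied more, so these shares do not measure an excess of changed probes. The count of changed probes was 2562 without clone 1, of which 1423 were higher and 1139 lower. It was 451 without clone 3, 32 without clone 4, and 18, 23, 31 and 17 without normal animals 1, 2, 3 and 4. It was 11447 with array weights, 146 with trend and robust settings, of which 86 were higher and 60 lower, 25 with normexp and quantile normalization, 17 with a filter on all 8 arrays, and 0 with normexp and 75th percentile centring, where 2278 probes had an unadjusted p under 0.05 and the median log2 change of all probes moved by -0.30.

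No transcript of the surfactant proteins passed the test between clones and normal animals. SFTPC, a hydrophobic surfactant protein of alveolar type II cells, measured 7.78 ± 0.23 in clones and 7.74 ± 0.10 in normal animals (log2, mean ± SD, n = 4 each), a log2 difference of 0.04 (95% interval -0.36 to 0.44). SFTPB, the other hydrophobic protein, differed by 0.04 (-0.40 to 0.48), the collectin SFTPA1 by -0.11 (-0.70 to 0.49) and the collectin SFTPD by 0.30 (-0.26 to 0.85). ABCA3, which carries lipid into lamellar bodies, differed by -0.04 (-0.76 to 0.67), and NKX2-1, a transcription factor of surfactant genes, by -0.31 (-0.91 to 0.29). With 1 animal left out SFTPD ranged from 0.11 to 0.43 and NKX2-1 from -0.47 to -0.0969. These values are those of the brightest probes. They are relative to each array's 75th percentile, a scale on which the spike-ins were 0.67 higher in clones. The other probes gave -0.53 and -0.62 for SFTPA1, -0.11 for SFTPB and -0.11 for ABCA3, and all 3 probes of NKX2-1 had the same sign. The adjusted p of these 6 genes lay between 0.657 for SFTPD and 0.971 for ABCA3. The sign of the differences in SFTPB and SFTPC turned with quantile normalization, to -0.13 and -0.32, as did that of SFTPA1 with normexp and 75th percentile centring, to 0.0107, and that of ABCA3, to 0.13.

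**Figure D2:**
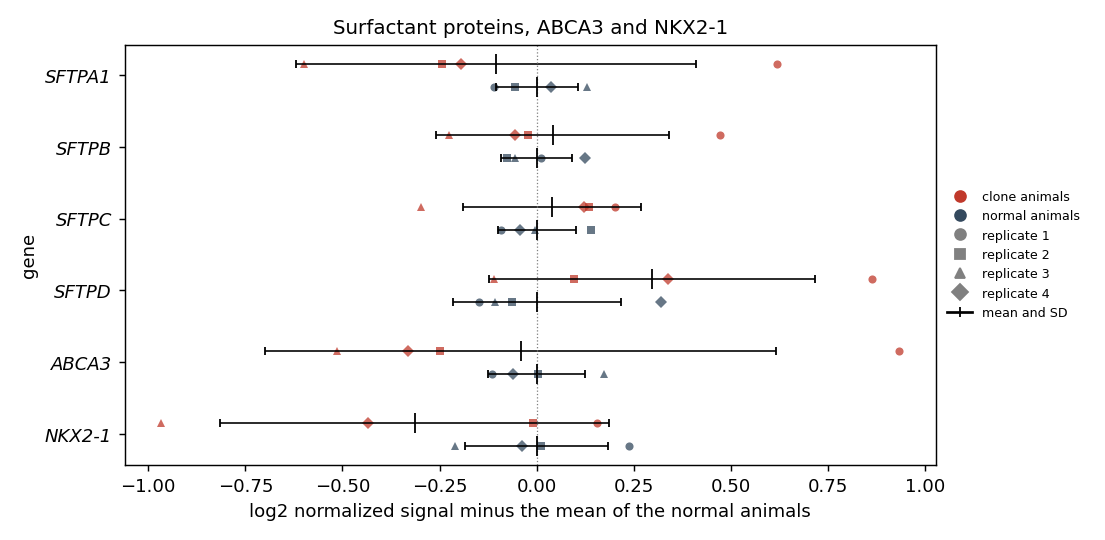
Log2 normalized signal of 4 surfactant proteins, the lipid transporter ABCA3 and the transcription factor NKX2-1, as the difference from the mean of the normal animals, for 4 clones (red) and 4 normal animals (dark blue); marker shapes give the replicate and black bars the mean and SD. The mean differences range from -0.31 for NKX2-1 to 0.30 for SFTPD, and the clones spread more widely than the normal animals, with SDs of 0.66 and 0.13 in ABCA3.

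The 4 lists of surfactant genes gave no call. Of 9 measured surfactant protein and lamellar body genes, 6 had a positive and 3 a negative log2 change, with a median of 0.04 (adjusted p = 0.477). The protease CTSH differed by 0.34 and the lysosomal membrane protein LAMP3 by 0.53 on the brighter of its 2 probes, which differed in sign. Among 21 genes of surfactant lipid synthesis the median was -0.13 (adjusted p = 0.342). ACACA, the rate-limiting enzyme of fatty acid synthesis, differed by -0.78 on its brightest probe (adjusted p = 0.234) while its other 2 probes had the opposite sign, and PCYT1A, the regulatory enzyme of phosphatidylcholine synthesis, by -0.41 (adjusted p = 0.401). The 13 genes of surfactant clearance had a median of -0.18 (adjusted p = 0.297), with NR1H3, a sterol-sensing receptor of macrophages, at -1.03 (adjusted p = 0.103) and PPARG at 0.50. The 13 regulators had a median of -0.02 (adjusted p = 0.502), with the receptor ERBB3 at -0.66 and the growth factor FGF7 at -0.73. With 1 animal left out CTSH ranged from 0.10 to 0.51, LAMP3 from 0.13 to 1.02 and FGF7 from -1.09 to -0.33. Over all probes 0 members of the 4 lists passed by limma, and 4 had an unadjusted p under 0.05. Adjusted over the list alone, NR1H3 was the sole member lower in clones. With an estimated correlation the adjusted p lay between 0.684 and 0.814, and by fry between 0.380 and 0.758.

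Proliferation genes had the highest median change of the lists over the 4 clones together, but not in clone 2 or clone 3 alone. All 19 measured cell cycle genes had a positive log2 change, with a median of 1.88 (camera adjusted p = 3.77e-08; adjusted p = 0.681 with an estimated correlation). The cyclin CCNB1 differed by 2.83, the ubiquitin-conjugating enzyme UBE2C by 2.69, the survivin gene BIRC5 by 2.09 and the mitotic kinase PLK1 by 1.01. Adjusted over the list alone, 4 of the 19 were higher, and over all probes 0 passed by limma and 10 had an unadjusted p under 0.05. The list's mean was above that of every normal animal in 3 of 4 clones, at -0.89 ± 1.46 in clones and -2.57 ± 0.60 in normal animals (log2, mean ± SD, n = 4 each). Without clone 1 the list's median was 1.20, and in normal animal 3 it was 1.03 above the other 3 normal animals.

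Genes induced by low oxygen shifted upward in all 4 clones relative to the 4 normal animals, from 1.63 ± 0.06 to 2.18 ± 0.28 in the list's mean (n = 4 each, exact permutation p = 0.0286, the smallest these groups allow, and 0.354 after adjustment over 31 lists). Of 21 hypoxia genes, 16 had a positive and 5 a negative log2 change, with a median of 0.57 (camera adjusted p = 0.000195; adjusted p = 0.681 with an estimated correlation). The glucose transporters SLC2A3 and SLC2A1 differed by 2.22 and 1.28 and the glycolytic enzyme GAPDH by 0.91, and adjusted over the list alone 4 members were higher. Without clone 3 the median was 0.28. In clones 1 to 4 alone the median was 0.21, 0.62, 0.68 and 0.26, and in normal animal 4 it was 0.11 against the other 3 normal animals. Of 16 matrix genes of fibroblasts, 13 had a positive log2 change and the median was 0.54 (camera adjusted p = 0.000195; adjusted p = 0.681 with an estimated correlation), with COL1A1 at 1.27, VCAN at 1.27 and FN1 at 1.02. The median of this list was 0.46, 0.59, 0.44 and 0.72 in clones 1 to 4 and 0.49 in normal animal 3 against the other 3 normal animals. Of 15 interferon response genes, 12 had a positive change with a median of 0.66 (camera adjusted p = 0.00738; adjusted p = 0.724 with an estimated correlation). Its members went both ways, with ISG15 at 2.07 and USP18 at 1.03 but IFIT3 at -1.83, and only clone 4 was above every normal animal. Without clone 4 the adjusted p of this list was 0.186 and the median 0.38, and normal animal 3 stood at 0.59 against the other 3 normal animals. Adjusted over the list alone, 0 matrix or interferon genes passed.

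Markers of ciliated airway cells were lower on balance in the clones. All 10 measured members had a negative log2 change, with a median of -0.97 (camera adjusted p = 5.82e-05; adjusted p = 0.681 with an estimated correlation), among them CCDC113 at -1.42 and RSPH1 at -1.33. Adjusted over the list alone 6 were lower, and the median in normal animal 3 was -0.96 against the other 3 normal animals. Of 15 neutrophil genes, 13 had a negative change with a median of -1.28 (camera adjusted p = 0.000400; adjusted p = 0.681 with an estimated correlation), with the cathelicidin CATHL5 at -2.53, the bactericidal protein BPI at -1.83 and the chemokine receptor CXCR2 at -0.68. The mean of the list was above that of every normal animal in clone 1, and the median change was -0.62 without clone 4. Of 13 macrophage genes, 12 had a negative change with a median of -0.56 (camera adjusted p = 0.000446; adjusted p = 0.681 with an estimated correlation), with the complement chains C1QB at -1.51 and C1QA at -1.24 and the lysosomal protein CD68 at -1.14. The medians were -0.93 and -1.23 in clones 2 and 4 but -0.0353 and -0.16 in clones 1 and 3, and only clones 2 and 4 were below every normal animal. Of 14 genes of lung fluid transport, 11 had a negative change with a median of -0.32 (camera adjusted p = 0.0410; adjusted p = 0.681 with an estimated correlation), and adjusted over the list alone 2 were lower, the sodium channel subunit SCNN1B at -1.62 and the aquaporin AQP3 at -1.37. The adjusted p of fluid transport was 0.113 without clone 4, and 0.0779, 0.0650, 0.0534 and 0.0513 without clone 1, clone 2, normal animal 1 and normal animal 2. No neutrophil or macrophage gene passed after adjustment over the list alone, and over all probes 0 members of any of the 31 lists passed by limma.

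The other 23 lists were not called by camera with 75th percentile centring of the processed signal. With quantile normalization, heat shock and unfolded protein genes, smooth muscle and chromatin methylation genes were called (adjusted p = 0.00225, 0.0272 and 0.0334). Those of lung and airway epithelium had medians of -0.07 for 14 genes of alveolar type I cells and -0.83 for 10 genes of airway secretory cells (adjusted p = 0.460 and 0.342), with HOPX at -1.18 and the secretory protein SCGB1A1 at -1.81. Adjusted over the list alone, 1 type I cell gene and 3 secretory cell genes were lower. Endothelial genes had a median of -0.18 (adjusted p = 0.358), with the carbonic anhydrase CA4 at -2.60 (adjusted p = 0.136) as the sole member lower when adjusted over the list alone. Smooth muscle had a median of -0.33, cardiac and skeletal muscle -0.17, T and NK cells -0.39, B and plasma cells 0.25 and erythroid cells 0.18 (adjusted p between 0.115 and 0.484). In the T and NK cell list, CD8A at -2.45 and GZMB at 1.25 passed only after adjustment over the list alone. The medians were 0.38 for inflammation, 0.65 for immediate early genes, -0.23 for glucocorticoid targets, -0.22 for heat shock and unfolded protein genes, -0.12 for NRF2 and oxidative stress genes and -0.37 for cholesterol synthesis (adjusted p between 0.0558 and 0.536). Adjusted over the list alone, 1 immediate early gene was higher. Inflammation ranged from -0.33 without clone 3 to 0.86 without clone 4 (adjusted p = 0.00294 in the latter), and stood at -0.72 with array weights (adjusted p = 0.0366). Immediate early genes ranged from 0.20 without clone 2 to 0.99 without clone 1 (adjusted p = 0.00596 in the latter). Endothelium ranged from -0.47 without clone 3 (adjusted p = 0.0359) to 0.17 without clone 1, and glucocorticoid targets from -0.50 without clone 3 (adjusted p = 0.0293) to 0.00474 without clone 4. Without clone 1 the median turned to -0.24 in B and plasma cells, 0.0112 in type I cells, -0.15 in coagulation and 0.19 in MHC class II. Imprinted genes had a median of 0.33, fetal genes 0.32 and chromatin methylation genes 0.25 (adjusted p = 0.0576, 0.170 and 0.0555). The mean of the chromatin methylation list was higher in all 4 clones than in any normal animal (n = 4 each, exact permutation p = 0.0286, the smallest possible, and 0.354 after adjustment). Leaving out 1 animal at a time gave medians of 0.16 to 0.56 for imprinted genes, 0.20 to 0.44 for fetal genes, -0.49 to -0.0822 for heat shock and unfolded protein genes, -0.25 to -0.0832 for NRF2 and oxidative stress genes, -0.45 to -0.11 for T and NK cells, 0.0615 to 0.59 for erythroid cells, -0.34 to -0.0671 for cardiac and skeletal muscle, -0.45 to -0.18 for smooth muscle, -0.89 to -0.0520 for cholesterol synthesis and -1.35 to -0.49 for secretory cells. In 2 lists the median and the test differed in sign. Coagulation had a median of 0.06, a mean of -0.28 and a downward test (adjusted p = 0.536), and MHC class II had a median of -0.10, a mean of 0.67 and an upward test (adjusted p = 0.852). In the latter, BOLA-DQA5 was well above background in all 4 clones and in 2 of 4 normal animals, so the size of its difference is not given (adjusted p = 0.141).

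**Figure D3:**
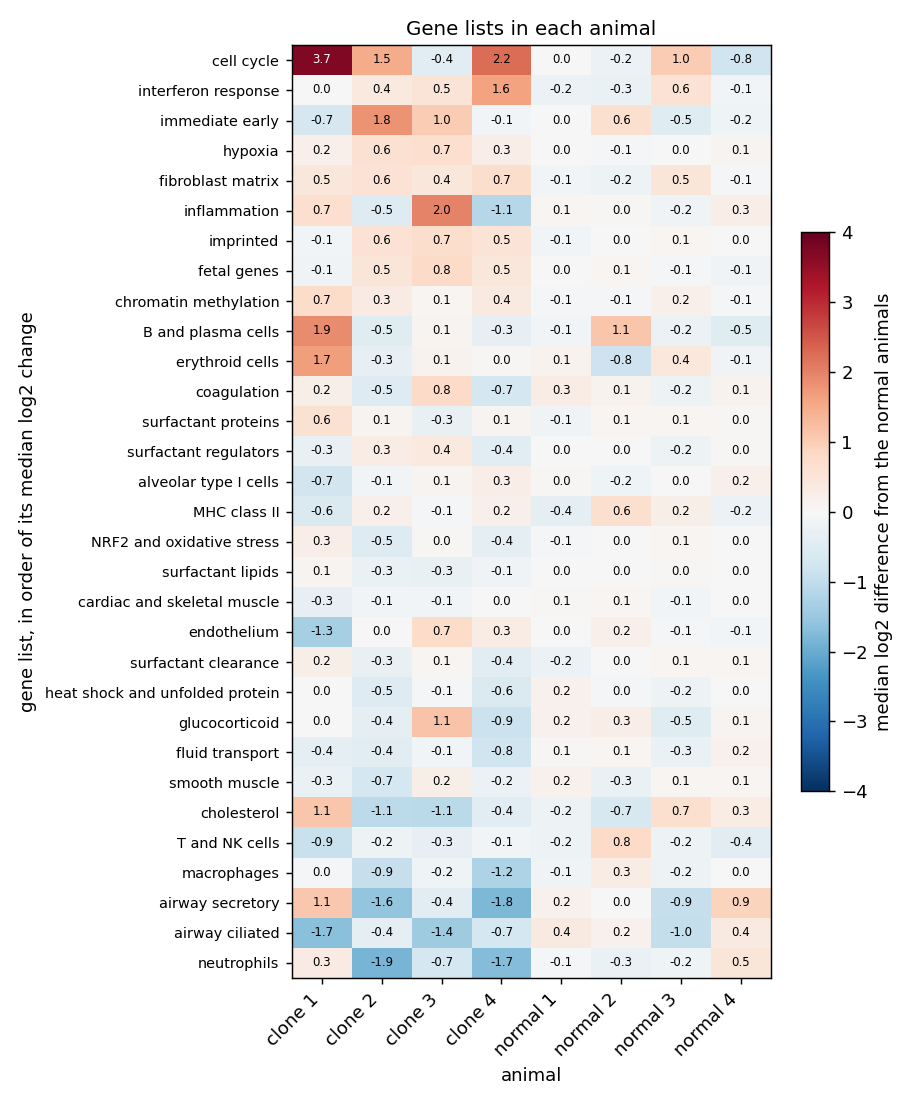
Median log2 difference from the normal animals of the measured members of each of 31 gene lists (rows) in each animal (columns), where a clone was set against all 4 normal animals and a normal animal against the other 3; red is higher and blue lower, on a scale from -4 to 4. Cell cycle genes range from -0.43 in clone 3 to 3.70 in clone 1, and neutrophil genes from -1.87 in clone 2 to 0.33 in clone 1.

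Apart from the pair of clones 2 and 4, the cloned animals differed from each other more than the normal animals did. Pairwise correlations of the arrays across kept probes lay between 0.907 and 0.988 among clones and between 0.984 and 0.989 among normal animals. Clones 2 and 4 correlated at 0.988, within the range of the normal animals, and the lower correlations were all in pairs with clone 1 or clone 3. The median SD of a probe was 0.53 among clones and 0.17 among normal animals (log2, n = 4 each), and 90.0% of probes were more variable among clones. Of the kept probes, 19.1%, 11.9%, 26.5% and 14.0% lay at least 2-fold from the mean of the normal animals in clones 1, 2, 3 and 4. Each normal animal had 2.08% to 3.05% of probes this far from the mean of the other 3. Cell cycle genes had a median of 3.70, 1.48, -0.43 and 2.22 in clones 1 to 4, inflammation genes 0.68, -0.51, 1.99 and -1.14, and endothelial genes -1.33, 0.02, 0.73 and 0.29.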

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

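The greater spread among clones, the lower chymosin signal and the larger count of calls without clone 1 are weighed here. Chosen after the results had been seen were the tests of the spread by splits and without clone 1, of the chymosin probes and of chymosin without 1 animal, and of the calls without clone 1. When the 8 animals were divided into 4 and 4 in all 35 ways, the real groups gave 63 changed probes and the highest other split 3, so that 1 split of 35 reached the real count, also for changes of at least 2-fold. For genes the values were 18 and 2, again with 1 split as large. For gene lists the real groups gave 8 calls and the highest other split 18, and 28 of 35 splits gave as many as the real groups, so chance is not excluded for the count of called lists.

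The median log2 ratio of clone to normal variance was 3.23, against 2.04 in the highest other split, and 1 split of 35 was as large. The spike-in probes, which carry the noise of slide and scan, gave -0.31. With each array's spike-in mean taken off they gave -0.53 (upper quartile 0.29). These values argue against more noise of the clone slide as a whole, although the spike-in level was 0.67 higher on the clone arrays. Each spike-in value averages 32 spots, so noise of single spots is not covered. The brightest probes gave 3.76, which argues against dim signal. The lowest ratio with 1 clone left out was 2.36, without clone 3, which argues against 1 stray array. Without clone 1 it was 2.37, which argues against the difference in DDX3Y and USP9Y signal among the clones. It was 3.47 without clone 2 and 3.42 without clone 4. Leaving out 1 array cannot exclude that clones 1 and 3 together carry the excess. Differences between the clones in tissue state, time of death or RNA quality were not tested and remain open beside a biological difference.

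The chymosin probe that changed least fell by 6.75, but it was well above background in only 1 of 4 clones, so this size is limited by background. The brightest probe, well above background in all 4 clones, changed by -6.97. The change nearest 0 with 1 animal left out was -6.40. Neither 1 faulty probe nor 1 animal accounts for the lower CYM signal. Of 14 other genes listed for stomach and on the array, 7 were well above background on all arrays of a group. Of the rest, GAST was well above background in 3 of 4 normal animals, GKN1 and KCNE2 in 1 each, and LIPF, ANXA10, VSIG1 and LYZ3 in 0. The median log2 change of the 7 was -0.70, with 3 lower by more than 1 and 1 higher by more than 1. TFF2 was at -2.12, LYZ2 at -1.31, PGA5 at -1.02, ATP4A at -0.70, PGF at -0.24, CLDN18 at -0.04 and GHRL at 1.53. CLDN18 is also in the list of type I cells, and the symbol PGF is that of placental growth factor. Neither therefore reports stomach alone, and the median depends on which genes are counted. On these values, stomach tissue or fluid in the normal samples and a difference in the lung itself cannot be told apart.

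Without clone 1 there were 2562 calls, and clone 1 moved the same way by at least 1 on the log2 scale in 13.4% of them and by any amount in 1257, while 1352 of the calls were themselves at least 2-fold. The share moving by at least 1 was 87.5% of 56 calls for clone 2, 34.6% of 451 for clone 3, with 325 moving the same way by any amount, and 96.9% of 32 for clone 4, and the calls without clones 2 and 4 were all at least 2-fold. Calls gained without an animal are by selection probes that it does not follow, so these shares decide nothing. Clone 1 was the only clone without signal of DDX3Y and USP9Y, which all normal animals also lacked. ZFY, at a like level in all 8 animals, does not separate animals with this signal from those without. For these calls a difference of sex between the groups and another difference of clone 1 from clones 2, 3 and 4 cannot be told apart.

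Of 186 group values examined for an animal far from the other 3 of its group, 13 stood out, where chance gives 9.3. Among genes these were ACSM1 at 2.71, CCDC113 at -0.39 and USP18 at -3.08 in normal animal 3, PDCL2 at -4.28 in normal animal 1, COL1A1 at 3.102 and SFTPC at 7.45 in clone 3, and SLC2A3 at 1.88 in clone 1. Among mean list values they were B and plasma cells at -0.87 in clone 1 and -2.05 in normal animal 2, T and NK cells at -2.92 in clone 1, smooth muscle at 2.52 in normal animal 2 and surfactant proteins at 3.95 in normal animal 1. The log2 75th percentile of signal was 10.59 in normal animal 2. Outside the tests, a signal appeared for the Y-linked DDX3Y and USP9Y, with mean differences of 5.28 and 6.32 between clones and normal animals, whose size is not measured, since clone 1 and all normal animals were at background.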

How the results depend on the processing

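By camera at the preset correlation, all 8 called lists kept their direction under every alternative, and only fluid transport and interferon response crossed the threshold, in fits with the block or with 1 animal left out. Among the lists without a call, heat shock and unfolded protein genes were called in 12 of 20 alternatives, chromatin methylation in 8, immediate early genes in 7, imprinted genes in 5 and smooth muscle in 4. T and NK cells were called in 3, and secretory cells, cholesterol synthesis, glucocorticoid targets and inflammation in 2 each. Cardiac and skeletal muscle, coagulation, endothelium, erythroid cells, fetal genes and NRF2 genes were called in 1 each, and no surfactant list in any. Without clone 1 cholesterol synthesis had a median of -0.89 (camera adjusted p = 0.00137). No list was called with an estimated correlation, by fry or by exact permutation of list scores (0 in each), the last chosen after seeing the data. The smallest permutation p these groups allow is 0.0286. After adjustment over 31 lists the permutation could call a list only if many reached that value together, and 2 did, so its 0 decides nothing. The main counts were 63 changed probes, 17 higher and 46 lower, all 63 at least 2-fold, and 18 genes. With normexp and 75th percentile centring all these counts were 0. With normexp and quantile normalization there were 25 probes, 7 higher and 18 lower, 20 of at least 2-fold, and 6 genes. With a filter on all 8 arrays there were 17 probes, 6 higher and 11 lower, 17 of at least 2-fold, and 6 genes. With trend and robust settings there were 146 probes, 86 higher, 95 of at least 2-fold, and 51 genes, so that 58.9% were higher against 27.0%. Array weights gave 11447 probes, 5585 higher and 5862 lower, 3471 of at least 2-fold, 3150 genes and 17 lists. Array weights with 1 weight per group, chosen after seeing the data, gave 13 probes, 1 higher and 12 lower, 13 of at least 2-fold, and 2 genes. The cause was not tested.

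The median of the surfactant regulators was -0.19 with normexp and 75th percentile centring and -0.23 with array weights, and that of surfactant clearance -0.44 with array weights; the cause was not tested. The sign of SFTPB turned to -0.13 with quantile normalization, -0.14 with normexp and quantile normalization, -0.13 in the authors' table, -0.0556 with array weights and -0.0365 with the mean of its probes. SFTPC turned to -0.32, -0.33 and -0.32 in the first 3 of these settings and CTSH to -0.0599, -0.00525 and -0.0575, and to -0.00478 with array weights. With normexp and 75th percentile centring SFTPA1 turned to 0.0107 and ABCA3 to 0.13; the cause was not tested.

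Leaving out 1 animal at a time gave 17 to 2562 probes, 4 to 1423 higher, 13 to 1139 lower, 17 to 1352 of at least 2-fold, 4 to 704 genes and 7 to 13 lists, with 55.5% of the probes higher without clone 1 and 0 to 0 surfactant lists. The medians ranged from -0.00305 to 0.15 for surfactant proteins, -0.30 to 0.00381 for lipids, -0.32 to -0.08 for clearance and -0.29 to 0.0811 for regulators. SFTPB ranged from -0.10 to 0.13, SFTPC from -0.0137 to 0.15, SFTPA1 from -0.35 to 0.0595 and ABCA3 from -0.37 to 0.12, with ABCA3 at 0.0281 without clone 2, 0.0558 without clone 4 and 0.0163 without normal animal 3.

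With the replicate number as a block there were 13 probes, 3 higher and 10 lower, 13 of at least 2-fold, and 4 genes. Animals of the same number correlated at 0.0915, 0.0991, -0.203 and -0.0987 in their deviations from the group means, and the own number was the best in 2 of 4, so the numbers do not pair the animals. No block for slide or scan was run, since each held 1 group. Signal over background limits the size of a change: 22 of the lower and 5 of the higher calls had no array well above background in the dimmer group.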

Other observations

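Clones 2 and 4 resembled each other. Their deviations from the normal animals correlated at 0.841 over kept probes, and at 0.743 to 0.799 when each was set against separate normal animals, while the other pairs of clones lay between 0.0662 and 0.251. The tests and the splits took the 4 clones as independent animals. If clones 2 and 4 were not independent, the p-values would overstate the evidence. Neutrophil genes had a median of -1.87 in clone 2 and -1.74 in clone 4, and macrophage genes -0.93 and -1.23. Secretory cell genes had -1.58 and -1.79. Clone 1 had 1.08 for secretory cells, 1.67 for erythroid cells, 1.90 for B and plasma cells, -0.90 for T and NK cells and 1.11 for cholesterol synthesis. Clone 3 had 1.99 for inflammation and 1.13 for glucocorticoid targets, and immediate early genes had 1.78 in clone 2 and 1.02 in clone 3. The first 3 principal components held 32.7%, 29.6% and 23.3% of the variance.

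Of 20 liver genes well above background in a group, 7 were lower in clones by more than 1 on the log2 scale and 0 higher, with a median of -0.15.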
